A study of Caenorhabditis elegans with 18 samples.

How the data were processed

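Total RNA of 18 samples of whole N2 hermaphrodites was made into libraries with the TruSeq RNA kit (v2), per the labels' protocols. Reads were demultiplexed with bcl2fastq 1.8.4, aligned with STAR 2.4.1d to WBcel235 and counted per gene with featureCounts 1.4.6-p4, per the submitters' processing notes. Strand setting, treatment of reads with several positions and annotation release are not given there. The deposited counts table holds raw read counts per gene, which were used for all main tests. The deposited RPKM table holds read counts scaled by gene length and a library total, named RPKM by its file, and served only as an alternative.

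The RPKM values were checked against the counts. Over 3514 genes with at least 20 RPKM in all libraries, each library's values give 1 gene length, within 0.00313%, when the divisors are the totals of all libraries recycled down the genes of the table. When each library's own total is the divisor, the lengths differ by a median of 35.8% and at most 54.3%. Hence 94.4% of the RPKM values were divided by the total of another library, at 0.628 to 1.59 times their own total, and no level is given in RPKM.

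Groups follow plasmid and age from the labels, with 3 libraries in each of 6 groups and no column left without a sample. The libraries were run on 7 lanes. L4440 day-1 replicate 1 and T14F9.5 day-1 replicate 2 carry the same index and lane in their descriptions, and their counts are not duplicates. By a chi-square per degree of freedom each is nevertheless the library closest to the other (58.4). L4440 day-1 replicate 1 was further from its nearest group mate, replicate 3 (80.7). A wrong description and mixed reads were not tested. Gene names and positions come from the Ensembl annotation of WBcel235, which holds 46449 of the 46748 gene identifiers and lacks 299. Those missing took 0.0701% to 0.166% of the counts, ribosomal RNA genes 0.0803% to 1.83%, and the 10 most abundant genes 5.93% to 10.6%.

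Differential expression was tested with edgeR 4.0.16 in R 4.3.3: all 18 libraries in 1 model with a term per group, filterByExpr (minimum count 10, 14735 genes kept), TMM factors, robust quasi-likelihood tests with 12 residual degrees of freedom (common dispersion 0.0815) and Benjamini-Hochberg adjustment within each comparison at 0.05. CPM are group means of TMM-scaled counts-per-million with their SD, and log2 values use a prior count of 2. The 9 comparisons are each plasmid against L4440 at each age, age in L4440, the plasmids against each other at each age, and plasmid by age interactions. The comparisons, 50 gene lists and the rule for named genes were fixed before the data were examined.

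Gene lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists, and again with the correlation estimated. In the comparisons of each plasmid with L4440 and of age in L4440, named genes are hlh-2, lin-32, M05B5.3 and the arginine kinases. To these the rule adds 8 rising and 8 falling genes of largest change past the threshold, with at least 5 CPM and no overlap between groups. For the direct comparisons and interactions the rule names only 4 rising and 4 falling genes, and no gene beforehand. For each list described it adds up to 4 members past the threshold, or the most abundant where none passed. Other genes are named as chosen after their values were seen. Overlap of the responses was set beside 10 simulations of unchanged groups against the same controls, with genes that vary independently.

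On simulated counts with 50 genes changed per fold size, the steps for M05B5.5 against L4440 at day 1 (14575 genes) recovered 2% of 1.5-fold, 52% of 2-fold, 92% of 4-fold and 96% of 8-fold changes. For age in L4440 (14556 genes) the shares were 6%, 56%, 96% and 100%. Only genes with a mean of at least 5 CPM were changed. The simulated genes vary independently and lack the deviations that genes of a real library share. These shares therefore do not tell which changes would be called in the real libraries, and 0 calls there do not exclude large changes. Alternatives fixed beforehand were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, a minimum count of 50, the compared groups alone, lane as a fixed or random term, limma on log2 of the deposited RPKM with a pseudocount of 1 or 0.1, leaving out the pair with the same index and lane, and leaving out each library. After seeing the data these were added: an offset for gene length (spline with 4 degrees of freedom), 2 surrogate variables (sva 3.50.0), leaving out the first day-5 library of each plasmid, leaving out those and L4440 day-1 replicate 2, and a term in the model for the first day-5 libraries as a block. For the overlap of the responses, dividing the controls between the plasmids and leaving out L4440 day-1 replicate 2 were also chosen then. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.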

Results

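RNA was sequenced from whole hermaphrodites of the wild-type strain N2 of Caenorhabditis elegans, fed bacteria that carry one of 3 RNAi plasmids and collected at an age of 1 or 5 days. L4440 is the empty feeding vector, so its libraries are the controls. M05B5.5 is hlh-2, the worm's single E-type (daughterless) basic helix-loop-helix factor. T14F9.5 is lin-32, an atonal-type basic helix-loop-helix factor needed for several classes of sensory neuron and a dimer partner of HLH-2. The 6 groups of plasmid and age hold 3 libraries each, 18 in all. Libraries held 27024193 to 43016293 counts. The labels do not state whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these samples.

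**Figure D1:**
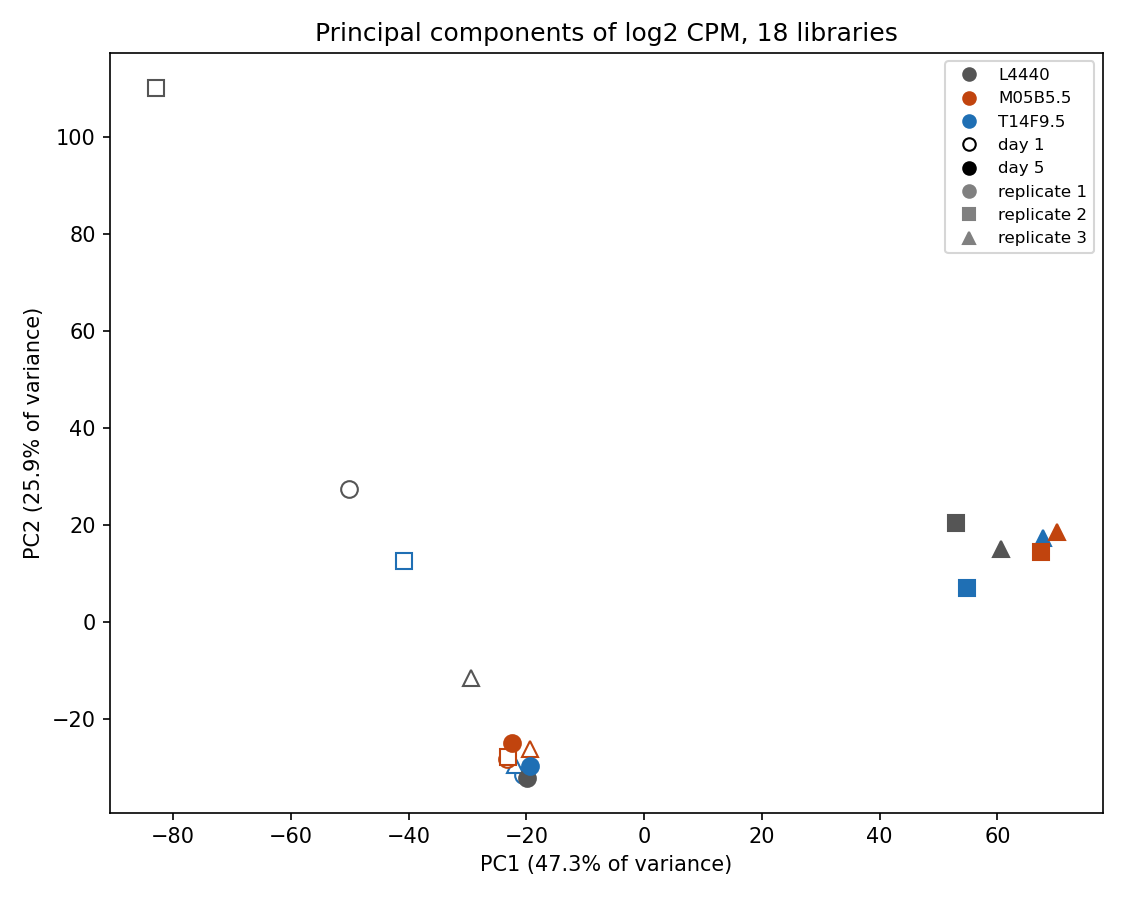
Position of each of the 18 libraries on the first 2 principal components of log2 counts-per-million, which carry 47.3% and 25.9% of the variance, with a colour for each plasmid, a symbol shape for each replicate, and open symbols for day 1 and filled ones for day 5. The first day-5 library of each plasmid lies among the day-1 libraries, and L4440 day-1 replicate 2 lies apart at 110 on the second component.

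The libraries of a group did not all lie together. On the first principal component the first day-5 library of each plasmid lay at -19.9 (L4440), -19.4 (T14F9.5) and -22.5 (M05B5.5), and the other day-5 libraries lay between 52.9 and 70.2. On the third component those 3 first libraries lay at 22.5 to 23.7, apart from the day-1 libraries (-19.8 to 9.12). L4440 day-1 replicate 2 lay at -83.0 on the first. It also stood apart by gene length: its log2 CPM, set against the mean of all libraries, dropped by 0.61 for each doubling of gene length.

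The transcript of hlh-2 was lower in every M05B5.5 library than in every L4440 library of the same age. hlh-2 (WBGene00001949, protein-coding, chromosome I from 7190788 to 7193920 on the minus strand, WBcel235) stood at 12 ± 0.68 counts-per-million (CPM; SD, n = 3) in the M05B5.5 day-1 libraries and at 41.3 ± 15.7 CPM in L4440. At day 5 it stood at 21.5 ± 9.33 CPM against 57.2 ± 3.02 CPM. The T14F9.5 libraries held 60.8 ± 5.57 CPM of hlh-2 at day 1 and 61.0 ± 6.62 CPM at day 5.

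The transcript of lin-32 was not lower in the libraries labelled T14F9.5. lin-32 (WBGene00003018, protein-coding, chromosome X from 2229055 to 2230122 on the minus strand) stood at 2.19 ± 0.246 CPM in the libraries labelled T14F9.5 and at 2.05 ± 0.456 CPM in L4440 at day 1. At day 5 its level was 3.75 ± 2.34 CPM (38, 174 and 207 counts) against 0.576 ± 0.360 CPM in L4440 of that age (34, 22 and 9 counts), higher in 3 of 3 libraries but in the first only by 38 against 34. Any direction given for lin-32 RNAi therefore refers to the libraries labelled T14F9.5, not to a measured loss of the transcript. M05B5.3 (WBGene00010871, chromosome I from 7185695 to 7188298 on the plus strand), which the series title names where the samples name M05B5.5, stood at 0.352 ± 0.0258 CPM in the M05B5.5 day-1 libraries and at 0.331 ± 0.0644 CPM in L4440.

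**Figure D2:**
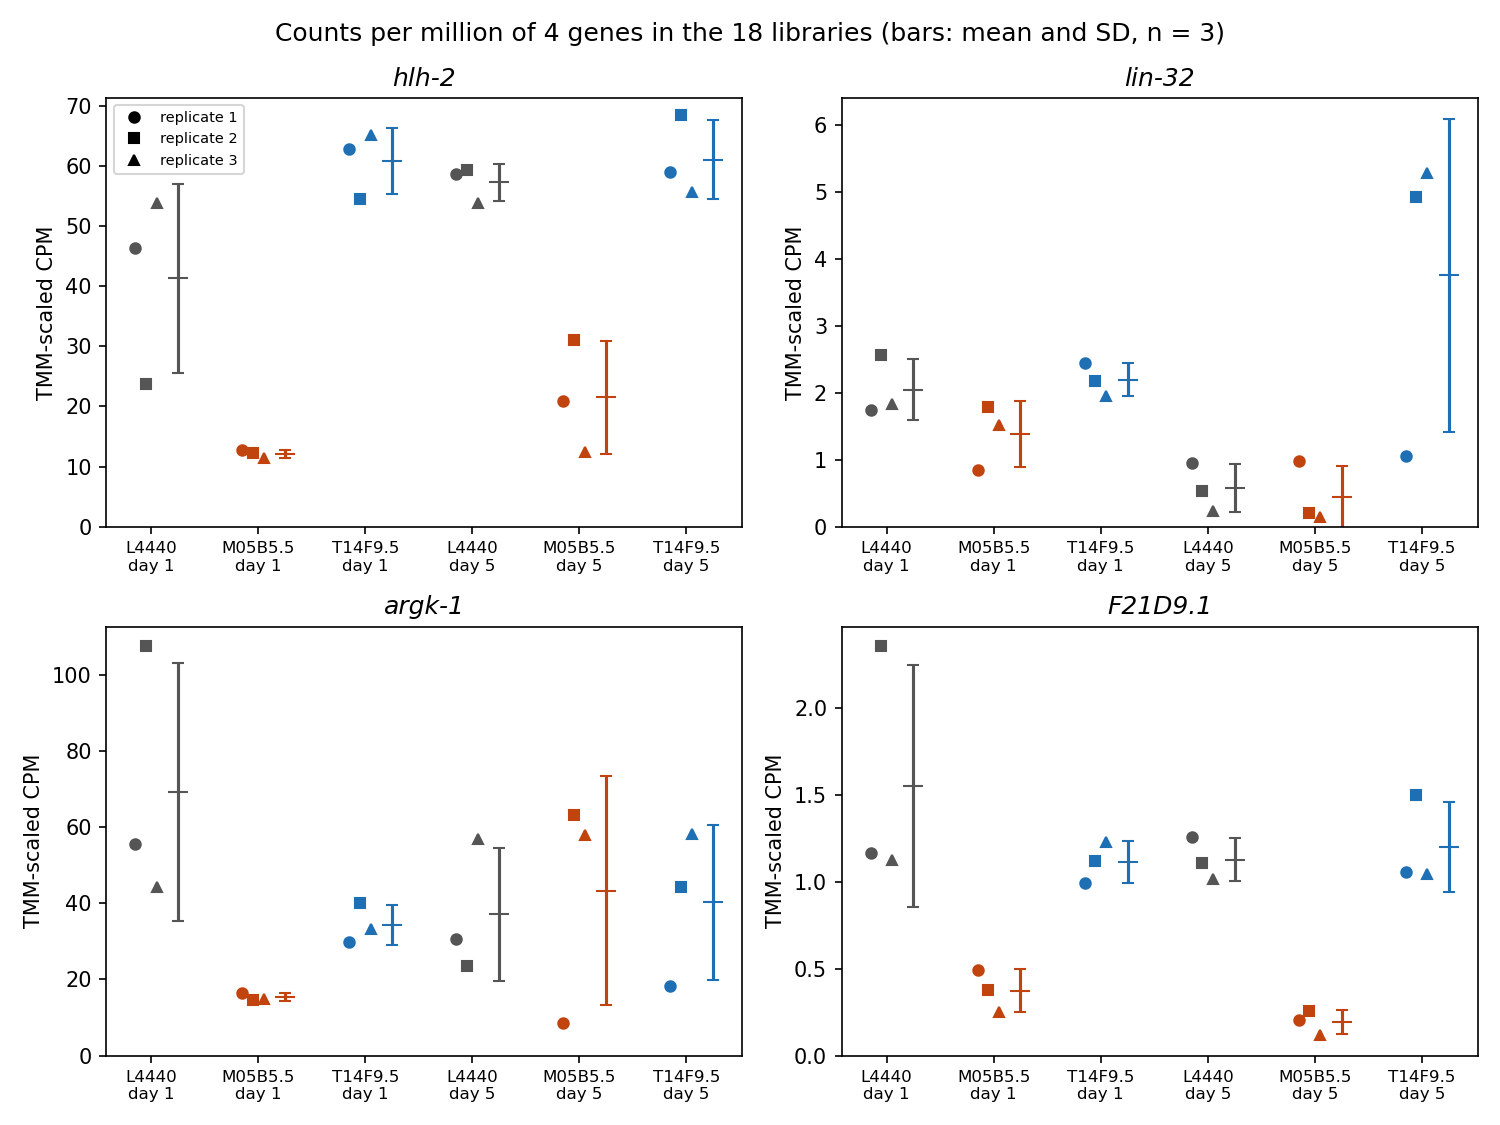
Level of hlh-2, lin-32, argk-1 and F21D9.1 in CPM in each library, by plasmid and age, with the mean and the SD of each group of 3 (bars are cut at 0). hlh-2 has its lowest group mean, 12 CPM, in the M05B5.5 day-1 libraries, and lin-32 its highest, 3.75 CPM, in the libraries labelled T14F9.5 at day 5.

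The comparison of M05B5.5 with L4440 at day 1 asks which transcripts go with the reduction of hlh-2 in young adults. These groups share no lane, so plasmid and lane cannot be told apart here. hlh-2 itself differed by a log2 fold change of -1.77 ± 0.29 (SE) and was lower in 3 of 3 libraries (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0709). argk-1, an arginine kinase, which buffers ATP through phosphoarginine, stood at 15.3 ± 1.02 CPM against 69.1 ± 33.8 CPM, a log2 fold change of -2.17 ± 0.59 (adjusted p = 0.0709). The other arginine kinases were at 0.21 (F46H5.3, adjusted p = 0.727), -0.47 (ZC434.8, adjusted p = 0.111) and -0.23 (W10C8.5, adjusted p = 0.780). cth-1, a cystathionine gamma-lyase of cysteine synthesis, stood at 50.3 ± 3.39 CPM against 116 ± 19.3 CPM (log2 fold change -1.2, adjusted p = 0.0709), and B0205.13 was at -1.66 (adjusted p = 0.0709). These 2 genes were chosen after their values were seen. The adjusted p of 0.0709 is the lowest of this comparison and is a value at which genes tie under the adjustment. It therefore does not set argk-1, cth-1 or B0205.13 on a par with hlh-2. No gene passed an adjusted p of 0.05 in edgeR: 0 of 14735, with 4685 under an unadjusted 0.05 where 737 would fall by chance. DESeq2 called 2244 genes and limma-voom with lane as a random effect 3515, with hlh-2, argk-1, cth-1 and B0205.13 among those of each. In the limma-voom fit the correlation within lanes was -0.24. Where the compared groups share no lane, a negative value lowers the standard errors, so the count of 3515 lends the calls no weight. On log2 RPKM, limma called 517 with 1 added to each value, 3 with 0.1 added and 0 when every gene above 0 was kept. RPKM are the deposited read counts scaled by gene length and a library total. Of them 94.4% were divided by another library's total, so limma's counts on RPKM do not bear on the result. With the first day-5 library of each plasmid as a block, a term picked from the same counts after seeing them, edgeR called 2311 genes, 883 up and 1428 down, and hlh-2, argk-1, cth-1 and B0205.13 were among them. With the same libraries left out instead, edgeR called 0 genes.

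The ribosomal proteins, the structural parts of the cytosolic ribosome, were lower as a group in the M05B5.5 day-1 libraries. Their median log2 fold change was -0.92 over 81 genes (camera, adjusted p = 2.2e-20, adjusted p = 0.666 with an estimated correlation). Of these genes 0 passed over all genes and 73 were lower when adjusted over the list alone. The most abundant, rpl-3, was at -0.11 (adjusted p = 0.679). In the control libraries the list's median log2 level, set against the mean of all libraries, was 0.53, 1.66 and 0.18, with the highest value in replicate 2, and in M05B5.5 it was 0.04, 0.01 and 0.01. Glutathione S-transferases, which conjugate toxic compounds, had a median of -0.71, with 4 of 37 lower adjusted over the list alone and gst-7 at -0.56 (adjusted p = 1.1e-06 for the list, adjusted p = 0.666 with an estimated correlation). Neuropeptide-like proteins, which include signalling peptides and antimicrobial peptides, had a median of -0.58, with 13 of 66 lower adjusted over the list alone and nlp-40 at -0.29 (adjusted p = 1.1e-06, adjusted p = 0.666 with an estimated correlation). nlp-27, a peptide of the epidermal antimicrobial cluster, was at -1.02 (adjusted p = 0.0709). FMRFamide-like neuropeptides had a median of -0.45, with 7 of 30 lower adjusted over the list alone and flp-6 at -0.23 (adjusted p = 3.6e-05, adjusted p = 0.666 with an estimated correlation). These medians shrank without L4440 day-1 replicate 2, to -0.34 for ribosomal proteins, -0.45 for glutathione S-transferases, -0.34 for neuropeptide-like proteins and -0.29 for FMRFamide-like neuropeptides, and the 4 lists passed. With an offset that takes out each library's trend against gene length, a choice made after seeing the data, they were -0.39, -0.30, -0.058 and -0.028, and neither neuropeptide list passed.

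Other groups were higher in the M05B5.5 day-1 libraries. The AMPK and TOR pathway, which couples growth to nutrients and energy, had a median of 0.63 over 24 genes, with 0 past the threshold adjusted over the list alone and let-363, the TOR kinase, at 1.14 (adjusted p = 2.2e-05 for the list, adjusted p = 0.666 with an estimated correlation). Dosage compensation and sex determination genes had a median of 0.59, with 5 of 21 higher adjusted over the list alone and mix-1, a condensin subunit, at 0.63 (adjusted p = 5.3e-05, adjusted p = 0.666 with an estimated correlation). Genes of the unfolded protein response of the endoplasmic reticulum had a median of 0.38, with 9 of 20 higher adjusted over the list alone and crt-1, calreticulin, at 0.07 (adjusted p = 0.00017, adjusted p = 0.666 with an estimated correlation). Larval moult genes had a median of 0.89 over 25 genes, with 0 adjusted over the list alone and noah-1, an apical matrix protein, at 1.60 (adjusted p = 0.00027, adjusted p = 0.666 with an estimated correlation). The AMPK and TOR median was 0.35 without L4440 day-1 replicate 2. With the gene length offset it was 0.37, the number of lists was 6, and the dosage compensation (0.11) and unfolded protein response (0.17) lists did not pass. DESeq2 called let-363, mix-1 and noah-1. In all, 23 of 50 lists passed, 13 up and 10 down, and 0 held with an estimated correlation. The lists described here and for the other comparisons are those of lowest adjusted p, and 1 more is named at its place. The count of genes depended on single controls: without L4440 day-1 replicate 3 edgeR called 5042 genes and without replicate 2 it called 1.

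The same comparison at day 5 asks what goes with the reduction of hlh-2 in older adults. hlh-2 was at -1.41 ± 0.29 on the log2 scale and lower in 3 of 3 libraries (adjusted p = 0.916). argk-1 was at 0.22 ± 0.57 (adjusted p = 1.00), with 8.63, 63.1 and 58 CPM in the M05B5.5 libraries and 30.7, 23.6 and 56.9 CPM in L4440. Among the other genes F21D9.1 had the lowest adjusted p, at 0.193 ± 0.0709 CPM against 1.13 ± 0.124 CPM (log2 fold change -2.55 ± 0.37, adjusted p = 0.0762). arrd-1, an arrestin-domain gene, was at -1.69 ± 0.37 (adjusted p = 0.968), and fbxb-42, an F-box gene, at -1.55 ± 0.35 (adjusted p = 1.00). F21D9.1, arrd-1 and fbxb-42 were chosen after their values were seen. edgeR called 0 of 14735 genes, with 200 under an unadjusted p of 0.05, below the 737 that would fall by chance. DESeq2 called 7, among them hlh-2, F21D9.1, arrd-1 and fbxb-42, limma on log2 RPKM 1, F21D9.1, and limma-voom 0. Of alternatives chosen after seeing the data, edgeR with surrogate variables called 14, with the same 4 genes among them, and edgeR with the first day-5 libraries as a block called 11, with F21D9.1, arrd-1 and fbxb-42 among them and without hlh-2.

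Major sperm proteins, the cytoskeletal proteins of nematode sperm, were lower in the M05B5.5 day-5 libraries as a group, with a median of -1.62 over 19 genes (camera, adjusted p = 2.1e-12, adjusted p = 0.503 with an estimated correlation). Their levels were low, with msp-76 at 0.0663 CPM against 0.286 CPM, and without L4440 day-5 replicate 2 the list no longer passed (median -0.51). Collagens of the cuticle had a median of -0.12 and a mean of -0.38 over 120 genes, with col-181 at 0.23 (adjusted p = 1.9e-08, adjusted p = 0.505 with an estimated correlation). Higher groups were the C-type lectins (median 0.20 over 115 genes, clec-87 at 0.05, adjusted p = 4.6e-07, adjusted p = 0.498 with an estimated correlation) and innate immunity genes (median 0.29 over 38 genes, adjusted p = 1.5e-06, adjusted p = 0.503 with an estimated correlation). lys-7, a lysozyme and the most abundant of the latter, was at 1.1 ± 1.02. Larval moult genes had a median of 0.40 over 25 genes, with noah-1 at 0.83 (adjusted p = 2.3e-06, adjusted p = 0.505 with an estimated correlation). Genes raised by the FOXO factor DAF-16, named here although other lists had a lower adjusted p, had a median of 0.39 over 19 genes, with sip-1 at 0.03 (adjusted p = 0.003, adjusted p = 0.672 with an estimated correlation). In these 6 lists 0 members passed adjusted over the list alone.

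Single libraries ended several of these calls. The DAF-16 list reversed to a median of -0.029 without M05B5.5 day-5 replicate 3, and no longer passed without M05B5.5 day-5 replicate 2 (0.33) or L4440 day-5 replicate 1 (0.18). Its level was -0.49, 0.83 and 0.99 in the M05B5.5 day-5 libraries and -0.38, 0.58 and 0.59 in L4440, with the low value in the first library of each. The innate immunity list no longer passed without L4440 day-5 replicate 1 (0.18) or M05B5.5 day-5 replicate 3 (0.10), nor the C-type lectins without L4440 day-5 replicate 2 (0.09). The collagen list passed throughout, but its median was 0.12 without L4440 day-5 replicate 1 and 0.078 without M05B5.5 day-5 replicate 3. It was -0.22 and -0.41 without L4440 day-5 replicates 2 and 3, and -0.99 and -0.031 without M05B5.5 day-5 replicates 1 and 2. Other medians moved without a loss of the call. Larval moult genes were at 0.26 without L4440 day-5 replicate 3 and at 0.22 and 0.67 without M05B5.5 day-5 replicates 2 and 3, and C-type lectins at 0.46 without L4440 day-5 replicate 1. Without M05B5.5 day-5 replicate 1 innate immunity genes were at 0.59 and the DAF-16 list at 0.71, and the latter was at 0.71 without L4440 day-5 replicate 3 as well. In all, 15 lists passed, 9 up and 6 down, and 0 held with an estimated correlation. Their number was 8 without L4440 day-5 replicate 2, 9 without M05B5.5 day-5 replicate 3 and 23 without M05B5.5 day-5 replicate 2.

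The libraries labelled T14F9.5 were compared with L4440 at day 1 to ask what goes with this plasmid in young adults. lin-32 was at 0.11 ± 0.62 on the log2 scale (adjusted p = 0.933), hlh-2 at 0.56 ± 0.28 (adjusted p = 0.249) and argk-1 at -1.01 ± 0.57 (adjusted p = 0.294). Ribosomal proteins were lower as a group, with a median of -0.80 over 81 genes, 59 of them lower adjusted over the list alone, and rpl-3 at -0.10 (camera, adjusted p = 1.1e-19, adjusted p = 0.646 with an estimated correlation). In the libraries labelled T14F9.5 that list's level was -0.10, 0.48 and -0.02, against 0.53, 1.66 and 0.18 in L4440. Major sperm proteins had a median of -2.29, with 10 of 19 lower adjusted over the list alone and msp-76 at 0.213 CPM against 2.25 CPM (adjusted p = 3.2e-07, adjusted p = 0.646 with an estimated correlation). Neuropeptide-like proteins had a median of -0.51 over 66 genes, with 0 adjusted over the list alone and nlp-27 at -0.99 (adjusted p = 3.8e-07, adjusted p = 0.646 with an estimated correlation). Glutathione S-transferases had a median of -0.63, with 4 of 37 lower adjusted over the list alone and gst-7 at -0.41 (adjusted p = 7.8e-07, adjusted p = 0.646 with an estimated correlation). FMRFamide-like neuropeptides had a median of -0.46, with 3 of 30 lower adjusted over the list alone and flp-6 at -0.07 (adjusted p = 2.5e-06, adjusted p = 0.646 with an estimated correlation). The medians shrank without L4440 day-1 replicate 2, to -0.22 for ribosomal proteins, -0.31 for neuropeptide-like proteins, -0.34 for glutathione S-transferases and -0.26 for FMRFamide-like neuropeptides, and these lists passed. With the gene length offset neither neuropeptide list passed (-0.11 and -0.066), and ribosomal proteins were at -0.34.

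Higher in the libraries labelled T14F9.5 at day 1 were the AMPK and TOR pathway (median 0.51 over 24 genes, let-363 at 0.99, adjusted p = 4.9e-06, adjusted p = 0.646 with an estimated correlation) and DNA replication and cell cycle genes. The latter had a median of 0.26, with 7 of 31 higher adjusted over the list alone and cyb-3, a B-type cyclin, at 0.24 (adjusted p = 3.7e-05, adjusted p = 0.646 with an estimated correlation). Dosage compensation and sex determination genes had a median of 0.47, with 4 of 21 higher adjusted over the list alone and mix-1 at 0.59 (adjusted p = 0.00016, adjusted p = 0.646 with an estimated correlation). The medians of these 3 lists were 0.27, 0.13 and 0.22 without L4440 day-1 replicate 2, and without replicate 3 they were 0.80, 0.44 and 0.80. The DNA replication list was at 0.39 without T14F9.5 day-1 replicate 2. With the gene length offset the dosage compensation list did not pass (0.11), and the number of lists was 12. In all, 25 lists passed, 15 up and 10 down, and 0 held with an estimated correlation. edgeR called 0 of 14735 genes, with 3357 under an unadjusted p of 0.05 where 737 would fall by chance. DESeq2 called 613, mix-1 and nlp-27 among them, and limma-voom and limma on log2 RPKM called 0. Without L4440 day-1 replicate 3 edgeR called 3883.

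The same comparison at day 5 asks what goes with this plasmid in older adults. lin-32 itself was at 2.71 ± 0.67 on the log2 scale in the libraries labelled T14F9.5 (adjusted p = 1.00). Larval moult genes were higher as a group, with a median of 0.55 over 25 genes and noah-1 at 0.54 (camera, adjusted p = 5.4e-08, adjusted p = 0.878 with an estimated correlation). That median was -0.01 and did not pass without T14F9.5 day-5 replicate 2. Epidermal antimicrobial peptides had a median of -0.59 over 13 genes, with nlp-27 at -0.26 (adjusted p = 0.00013, adjusted p = 0.878 with an estimated correlation). They no longer passed without L4440 day-5 replicate 3 (-0.10) or T14F9.5 day-5 replicate 1 (-0.37). Glutathione S-transferases had a median of -0.15 over 37 genes, with gst-7 at 0.09 (adjusted p = 0.00037, adjusted p = 0.878 with an estimated correlation). They no longer passed without L4440 day-5 replicate 1 (-0.05), T14F9.5 day-5 replicate 2 (-0.10) or T14F9.5 day-5 replicate 3 (-0.10). Other medians moved without a loss of the call: larval moult genes to 0.86 without T14F9.5 day-5 replicate 3, antimicrobial peptides to -1.08 without L4440 day-5 replicate 1 and -0.93 without T14F9.5 day-5 replicate 3, and glutathione S-transferases to -0.26 without L4440 day-5 replicate 2 and -0.29 without T14F9.5 day-5 replicate 1. In these 3 lists 0 members passed adjusted over the list alone, and among genes of touch receptor neurons mec-12, an alpha-tubulin, was at 0.12. In all, 11 lists passed, 8 up and 3 down, and 0 held with an estimated correlation. Their number was 22 without L4440 day-5 replicate 1 and 17 without T14F9.5 day-5 replicate 3. edgeR called 0 of 14735 genes, with 93 under an unadjusted p of 0.05, below the 737 that would fall by chance, and DESeq2, limma-voom and limma on log2 RPKM also called 0. Without the first day-5 library of each plasmid, a choice made after seeing the data, edgeR called 1 gene, lin-32, at 3.70, and with those libraries as a block it called 0.

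Age in L4440 asks which transcripts differ between day-5 and day-1 adults on the empty vector. Ribosomal proteins fell: 78 of 81 were lower, 81 adjusted over the list alone, with rpl-15 at -1.34, rpl-39 at -1.48, rps-28 at -1.53 and rpl-25.1 at -1.24. The list's median was -1.24 (camera, adjusted p = 8.8e-31, adjusted p = 0.609 with an estimated correlation). Its level was 0.53, 1.66 and 0.18 in the day-1 libraries and -0.11, -0.31 and -0.51 in the day-5 libraries. Subunits of the respiratory chain encoded in the nucleus fell in 34 of 61 cases and rose in 1 (40 and 2 adjusted over the list alone). Examples are cox-6C at -1.29, cox-6B at -1.16, ndub-3 at -1.18 and ucr-11 at -1.18 (list median -0.57, adjusted p = 3.9e-09, adjusted p = 0.609 with an estimated correlation). FMRFamide-like neuropeptides fell in 14 of 30 cases (22 adjusted over the list alone), among them flp-19 at -0.81 and flp-5 at -0.95 (list median -0.72, adjusted p = 1.4e-08, adjusted p = 0.609 with an estimated correlation). Neuropeptide-like proteins fell in 22 of 66 cases (33 lower and 1 higher adjusted over the list alone), among them nlp-33 at -1.76 and nlp-41 at -1.64 (list median -0.68, adjusted p = 1.6e-07, adjusted p = 0.609 with an estimated correlation). Glutathione S-transferases fell in 14 of 37 cases (18 adjusted over the list alone), among them gst-38 at -1.83 and gst-13 at -1.51 (list median -0.86, adjusted p = 4.0e-08, adjusted p = 0.609 with an estimated correlation). Major sperm proteins fell in 5 of 19 cases (10 adjusted over the list alone), among them msp-78, at 0.118 CPM against 1.56 CPM (list median -2.12, adjusted p = 1.6e-05, adjusted p = 0.609 with an estimated correlation). When L4440 day-1 replicate 2 was left out, which took the count of called genes to 0, the list medians were -0.65 for ribosomal proteins, -0.34 for the respiratory chain and -0.45 for neuropeptide-like proteins. There rpl-15 was at -0.83, rpl-39 and rps-28 at -0.88, cox-6C at -0.70, cox-6B at -0.60, ndub-3 at -0.75, ucr-11 at -0.64 and nlp-41 at -1.08. The major sperm protein median was -3.59 without L4440 day-5 replicate 2. That list did not pass without the first day-5 libraries and L4440 day-1 replicate 2, a choice made after seeing the data, with 1 of 20 genes lower and a median of -1.45. With the gene length offset neuropeptide-like proteins did not pass (-0.24).

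Groups that rose with age in L4440 include the AMPK and TOR pathway, with 6 of 24 genes up (10 adjusted over the list alone). Among them were rict-1, the Rictor homolog, at 1.21, mlst-8 at 1.13 and aak-1, a catalytic AMPK subunit, at 0.72 (list median 0.67, adjusted p = 1.8e-06, adjusted p = 0.609 with an estimated correlation). RNAi and small RNA genes rose in 11 of 38 cases (14 higher and 1 lower adjusted over the list alone). The Argonautes ergo-1 at 1.09 and sago-1 at 0.88, the RNA-dependent RNA polymerase rrf-1 at 0.72 and the helicase drh-1 at 0.52 were among them (list median 0.53, adjusted p = 1.8e-06, adjusted p = 0.609 with an estimated correlation). Dosage compensation and sex determination genes rose in 6 of 21 cases (9 higher and 1 lower adjusted over the list alone), with dpy-28 at 1.12, dpy-26 at 0.82, mix-1 at 0.71 and sdc-1 at 0.44 (list median 0.52, adjusted p = 0.00017, adjusted p = 0.609 with an estimated correlation). Oocyte and germ line genes rose in 6 of 48 cases and fell in 1 (9 and 1 adjusted over the list alone), with rec-8, a meiotic cohesin, at 0.77 and puf-7 at -0.49 (list median 0.27, adjusted p = 0.00031, adjusted p = 0.649 with an estimated correlation). Leaving out L4440 day-1 replicate 2 gave list medians of 0.41 for the AMPK and TOR pathway, 0.31 for RNAi and small RNA and 0.12 for oocyte and germ line genes. Dosage compensation was at 0.92, oocyte and germ line genes at 0.44 and mlst-8 at 1.76 without L4440 day-1 replicate 3. Without the first day-5 libraries and L4440 day-1 replicate 2 the dosage compensation list did not pass (median 0.31, 7 genes higher and 2 lower). With the gene length offset, likewise chosen after seeing the data, drh-1 was at -0.086 and sdc-1 at -0.25, and the lists of RNAi and small RNA (0.051), dosage compensation (0.061) and oocyte and germ line genes (0.069) did not pass.

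Single genes are given here by size of change among those past the threshold with at least 5 CPM and no overlap between groups. In L4440 with age, cnc-6, a caenacin antimicrobial peptide, rose to 5.01 ± 5.11 CPM from 0.0709 ± 0.0370 CPM (log2 fold change 6.02 ± 1.55, adjusted p = 0.0357). T22B7.7 rose to 144 ± 142 CPM from 6.28 ± 1.06 CPM (4.53), and F48C1.9 (4.22), Y47H10A.5 (3.72), WBGene00019958 (3.05) and C07E3.3 (3.02) rose as well. The ribosomal RNA gene rrn-3.1 (2.90) and F31C3.10 (3.15), an annotated pseudogene on the same end of chromosome I, were higher too, with rrn-3.1 at 9167 ± 8629 CPM against 1228 ± 809 CPM. In T14F9.5 all ribosomal RNA genes took 0.0875%, 0.138% and 0.385% of the counts at day 1 and 0.337%, 1.18% and 0.356% at day 5. In M05B5.5 they took 0.0925%, 0.270% and 0.0855% at day 1 and 0.712%, 0.478% and 0.0803% at day 5. The ages overlapped in both, so the rise of rrn-3.1 in L4440 is not shown to be a response to age. By the same limits the genes that fell most were F23A7.8 (-2.28), cpg-9 (-2.23), nspe-1 (-2.11), C36C9.10 (-2.06), C03D6.9 (-2.05), K08D9.9 (-2.04), F46E10.2 (-2.02) and linc-76 (-2.0). cpg-9 encodes a chondroitin proteoglycan. When L4440 day-1 replicate 2 was left out, F23A7.8 was at -1.48, C36C9.10 at -1.28, K08D9.9 at -1.2 and linc-76 at -1.02, and without L4440 day-5 replicate 1, rrn-3.1 was at 1.78 and F31C3.10 at 2.01. vit-6, a vitellogenin, was at 0.26 ± 0.28 (adjusted p = 0.50), argk-1 at -0.90 ± 0.57 (adjusted p = 0.249) and lin-32 at -1.83 ± 0.67 (adjusted p = 0.0677). Of these 3, DESeq2 called lin-32. The direction of vit-6 is not settled: it was at -0.088 without L4440 day-5 replicate 1, and at -0.80 and called with the gene length offset and without the first day-5 libraries, a choice made after seeing the data (adjusted p = 0.0301, with 0.0301 to 0.990 over its alternatives).

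edgeR called 2332 of 14735 genes for age in L4440, 990 up and 1342 down, with a lowest adjusted p of 0.0355. The day-1 and day-5 libraries of L4440 share no lane, so age and lane cannot be told apart. Several alternatives ended these calls. The count was 0 with the compared groups alone and 0 without the pair sharing index and lane. It was 0 with the gene length offset too, chosen after seeing the data. The RPKM settings gave 3, 0 and 0 (1 added, 0.1 added, every gene above 0). Of the RPKM values 94.4% were divided by another library's total, so those counts say nothing about the calls. The count was 715 with no filter on low counts, 3807 with DESeq2 and 4735 with limma-voom and lane. The correlation within lanes in the limma-voom fit was -0.24. It lowers the standard errors where the groups share no lane, so the count of 4735 lends the calls no weight. With upper-quartile factors the split was 816 up and 2115 down. In all, 18 lists passed, 8 up and 10 down, and 0 held with an estimated correlation. The count of genes was 0 without L4440 day-1 replicate 1 or 2, 0 without L4440 day-5 replicate 2 or 3, and 5533 without L4440 day-1 replicate 3. Without the first day-5 libraries and L4440 day-1 replicate 2, a choice made after seeing the data, it was 4548, of which 1576 were among the 2332. With the first day-5 libraries as a block, chosen likewise, it was 6240, with 2331 of the 2332 among them. The first day-5 libraries were picked because they lie near day 1. Taking them out widens the age difference by design, so these counts and those below lend the calls no weight. In the libraries that remain without the first day-5 libraries and L4440 day-1 replicate 2, 74 of 81 ribosomal proteins and 8 of 21 pharynx genes were lower at day 5. So were 4 of 6 vitellogenins, which are yolk proteins, and 0 of these lists' genes were higher. Of 30 muscle genes 17 were lower and 1 higher, of 19 genes raised by DAF-16 10 were higher and 2 lower, and of 13 epidermal antimicrobial peptides 7 were higher and 1 lower. These 6 lists were chosen after their values were seen.

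**Figure D3:**
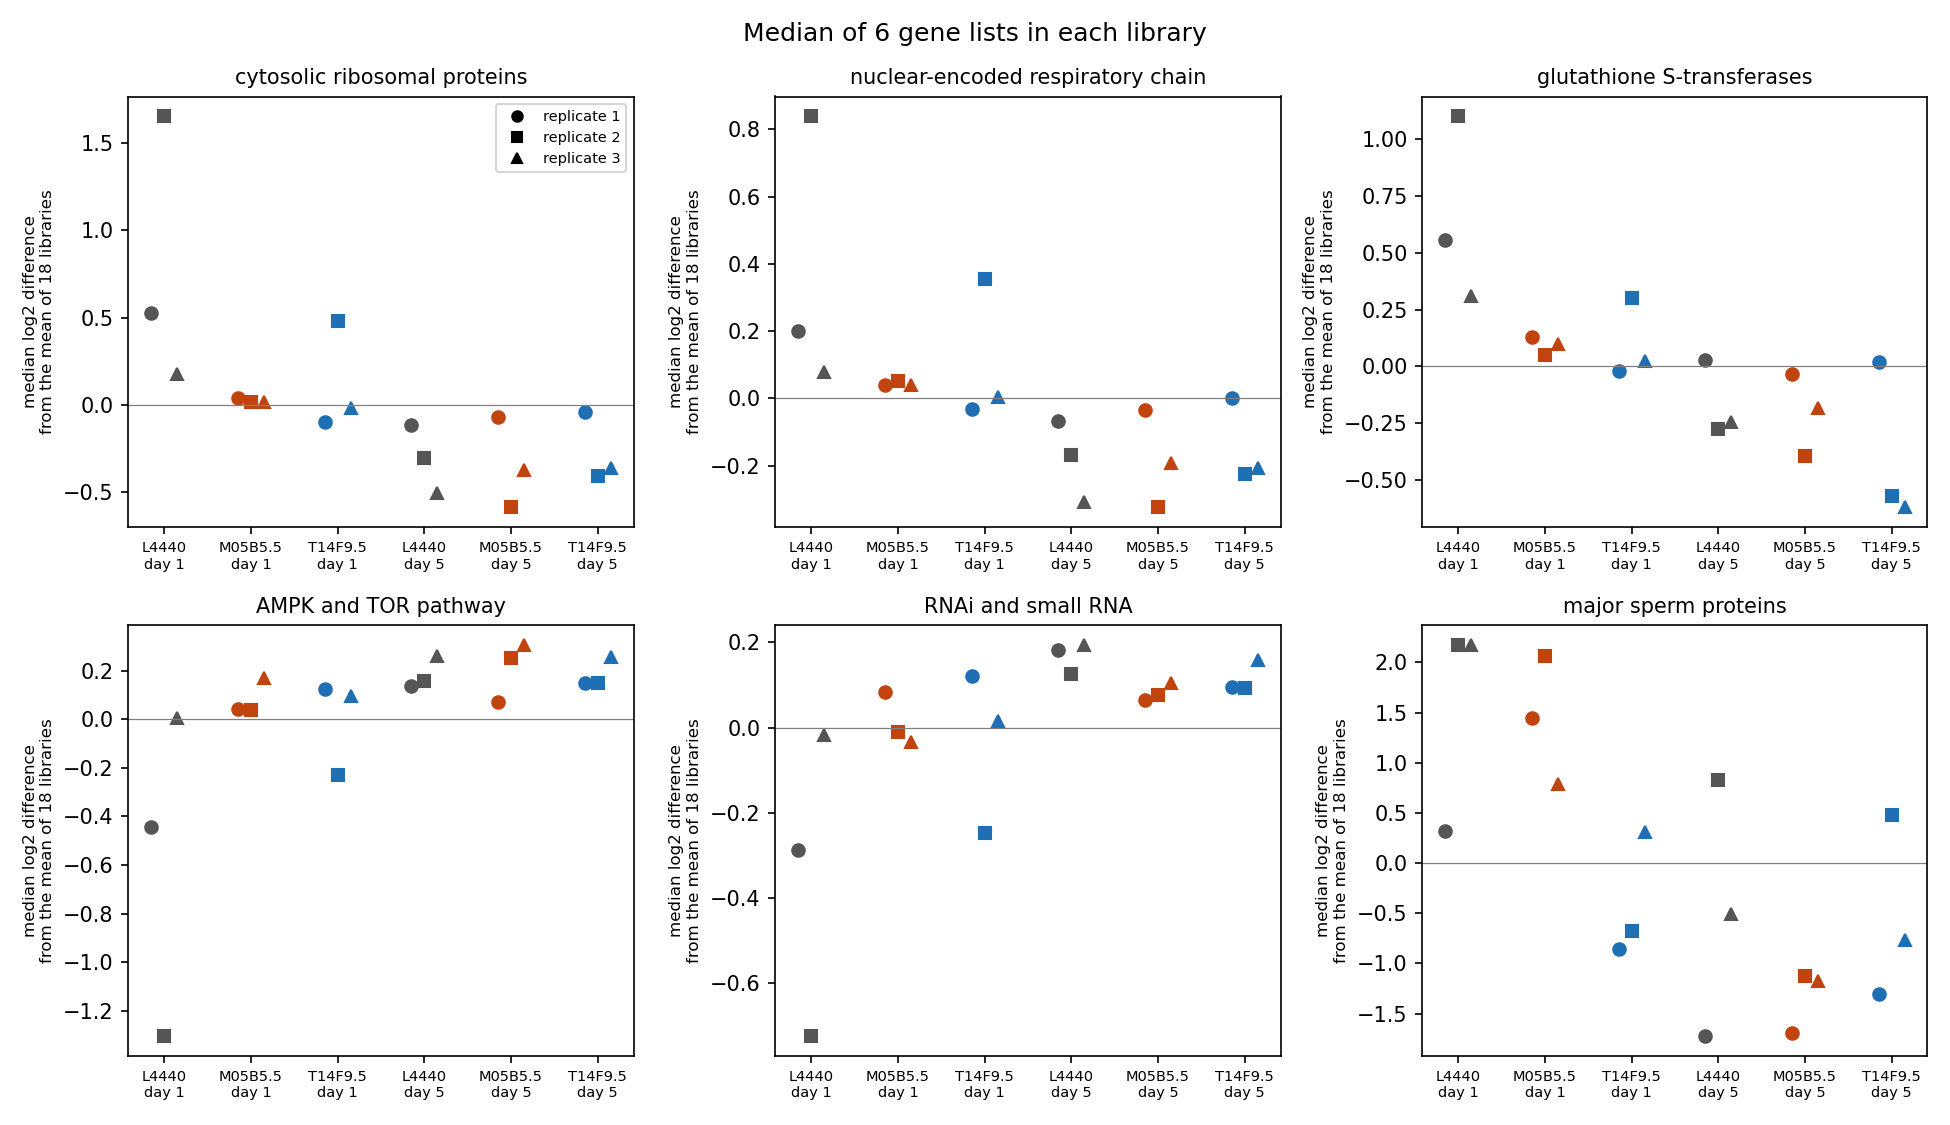
Median log2 level of 6 gene lists in each of the 18 libraries, set against the mean of all libraries, grouped by plasmid and age. In L4440 day-1 replicate 2 the ribosomal proteins are at 1.66, their highest, and the AMPK and TOR pathway list is at -1.3, its lowest.

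M05B5.5 was compared directly with the libraries labelled T14F9.5 to ask where the plasmids part. The day-1 groups share no lane, so plasmid and lane cannot be told apart at that age. At day 1 hlh-2 fell by 2.33 ± 0.30 on the log2 scale, the single gene of 14735 that edgeR called (adjusted p = 0.0155, lower in 3 of 3 libraries), with 142 genes under an unadjusted p of 0.05, below the 737 that would fall by chance. Major sperm proteins were higher in M05B5.5, with a median of 2.08 and 9 of 19 higher adjusted over the list alone (camera, adjusted p = 3.0e-33, adjusted p = 0.152 with an estimated correlation). Larval moult genes had a median of 0.63 over 25 genes, with 0 adjusted over the list alone (adjusted p = 2.0e-07, adjusted p = 0.873 with an estimated correlation). F58D2.1, an annotated pseudogene, was at -3.83, fbxb-38 at -1.73, arrd-1 at -1.55 and fbxb-42 at -1.39, each with an adjusted p of 1.00. These 4 were chosen after their values were seen. edgeR on the libraries of these 2 groups alone called all 4 among its 6 genes, and DESeq2 called 3 genes, F58D2.1 among them. With the first day-5 libraries as a block edgeR called 4, F58D2.1, fbxb-38, fbxb-42 and hlh-2. The larval moult median was 0.33 without T14F9.5 day-1 replicate 2, 0.96 without T14F9.5 day-1 replicate 3 and 0.35 without M05B5.5 day-1 replicate 3, and the list passed in each. In all, 9 lists passed, 4 up and 5 down, and 0 held with an estimated correlation. Their number was 14 without T14F9.5 day-1 replicate 1 and 5 without M05B5.5 day-1 replicate 3. The call of hlh-2 ended, at 0 genes, without T14F9.5 day-1 replicate 1 or 3 and without M05B5.5 day-1 replicate 1, 2 or 3.

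At day 5 the direct comparison gave the lowest adjusted p to F21D9.1, at -2.64 ± 0.37 on the log2 scale (adjusted p = 0.0505). arrd-1 was at -2.0 ± 0.37 (adjusted p = 0.349), fbxb-42 at -1.59 ± 0.35 (adjusted p = 0.535), hlh-2 at -1.51 ± 0.29 (adjusted p = 0.377) and lin-32 at -3.1 ± 0.69 (adjusted p = 0.535). tbb-4, a beta-tubulin of ciliated neurons, stood at 0.514 ± 0.0825 CPM against 8.67 ± 10.2 CPM (-4.07, adjusted p = 0.535). These 6 genes were chosen after their values were seen. Collagens had a median of -0.40 over 120 genes (camera, adjusted p = 8.4e-14, adjusted p = 0.630 with an estimated correlation), and under a stricter filter on low counts their median was 0.16 and the list did not pass. Major sperm proteins had a median of -1.70 over 19 genes (adjusted p = 6.9e-11, adjusted p = 0.630 with an estimated correlation). F-box and MATH-BTB genes, adaptors of protein breakdown, had a median of -0.02 and a mean of -0.18, with 4 of 298 lower adjusted over the list alone (adjusted p = 2.3e-08, adjusted p = 0.630 with an estimated correlation). edgeR called 0 of 14735 genes, with 285 under an unadjusted p of 0.05, below the 737 that would fall by chance. DESeq2 called 16, all 6 named genes among them, limma on log2 RPKM 1, F21D9.1, and limma-voom 0. With the first day-5 libraries as a block edgeR called 14, with F21D9.1, arrd-1 and fbxb-42 among them. Without M05B5.5 day-5 replicate 1 edgeR called 2. Without T14F9.5 day-5 replicate 2 the median of collagens was -0.096 and that of major sperm proteins -0.42. Collagens were at -0.70 without T14F9.5 day-5 replicate 3, and at -1.04 and -0.22 without M05B5.5 day-5 replicates 1 and 3. The median of F-box and MATH-BTB genes ran from -0.11 (without M05B5.5 day-5 replicate 2) to 0.0066 (without T14F9.5 day-5 replicate 2). These lists passed in each case. In all, 25 lists passed, 11 up and 14 down, and 0 held with an estimated correlation. Their number was 12 without M05B5.5 day-5 replicate 3.

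The interaction of plasmid and age asks whether the difference from L4440 changed between day 1 and day 5. For M05B5.5 it cannot be parted from lane, since the day-1 groups of M05B5.5 and L4440 share no lane. For M05B5.5, argk-1 had an interaction of 2.4 ± 0.81 on the log2 scale (adjusted p = 0.380) and hlh-2 one of 0.36 ± 0.40 (adjusted p = 0.657). Ribosomal proteins had a median interaction of 0.88 over 81 genes (camera, adjusted p = 1.4e-17, adjusted p = 0.607 with an estimated correlation). Neuropeptide-like proteins had 0.66 over 66 genes (adjusted p = 9.2e-08, adjusted p = 0.607 with an estimated correlation). For the libraries labelled T14F9.5, lin-32 had an interaction of 2.60 ± 0.91 (adjusted p = 0.670). Ribosomal proteins had a median of 0.84 (adjusted p = 8.0e-23, adjusted p = 0.657 with an estimated correlation), and major sperm proteins one of 2.33 over 19 genes (adjusted p = 5.1e-07, adjusted p = 0.657 with an estimated correlation). argk-1, hlh-2 and lin-32 are named here by choice after their values were seen, and in these 4 list results 0 members passed adjusted over the list alone. edgeR called 0 genes for M05B5.5, with 1923 under an unadjusted p of 0.05, and 0 for T14F9.5, with 765, where 737 would fall by chance in each. DESeq2, limma-voom and limma on log2 RPKM also called 0 for each. Without L4440 day-1 replicate 3 edgeR called 2128 and 599. In all, 24 lists passed for M05B5.5 and 25 for T14F9.5, and 0 held with an estimated correlation. The latter number was 15 without L4440 day-1 replicate 2. Without that library the ribosomal medians were 0.31 for M05B5.5 and 0.25 for T14F9.5, and that of neuropeptide-like proteins 0.40. The latter list did not pass with the gene length offset (0.17). Major sperm proteins were at 1.5 without L4440 day-5 replicate 1 and at 1.11 without T14F9.5 day-5 replicate 2.

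The log2 fold changes of the M05B5.5 and T14F9.5 libraries against the same L4440 libraries had a correlation of 0.889 at day 1, across 14105 genes, which are not independent replicates. In this fit of the day-1 libraries alone, 943 genes were higher in both and 1301 lower in both under an unadjusted p of 0.05, where simulated groups with no response gave means of 90.5 and 63.8, and 3 genes were lower in M05B5.5 at an adjusted p of 0.05. Shared controls alone give a positive correlation: treated groups simulated with no response and with genes that vary independently, set against the same 3 controls, gave a mean of 0.508 (0.484 to 0.526 in 10 simulations). Without L4440 day-1 replicate 2, a choice made after seeing the data, the correlation was 0.763. Such simulations with the other 2 controls gave 0.604 (0.592 to 0.622). The covariance went from 0.301 (simulated 0.0600) to 0.141 (simulated 0.0540). At day 5 the correlation was 0.288 over 14211 genes, below the simulated mean of 0.498 (0.477 to 0.514), with a covariance of 0.0226 (simulated 0.0967). The simulations do not carry deviations that genes of a library share, such as the gene length trend of L4440 day-1 replicate 2, and they draw the libraries of a group alike, although each day-5 group holds 1 library close to the day-1 libraries, which widens the spread they start from. Hence neither the excess at day 1 nor the lower value at day 5 can be read as a response to the plasmids or its absence. Part of the excess at day 1 may come from the shared controls. With 1 control for one plasmid and the other 2 for the other, a division chosen after seeing the data, the 6 possible correlations of differences in mean log2 CPM had a mean of 0.543 at day 1 (0.111 to 0.736) and of -0.408 at day 5 (-0.612 to -0.187), where all 3 controls for both gave 0.920 and 0.316. They vary with the control that stands alone, and no such division keeps 2 libraries on each side. At day 5 each group holds 1 library close to the day-1 libraries, so a division sets the differences on opposite sides of the gap between the ages. The negative values there were strongest with L4440 day-5 replicate 1 alone (-0.612 and -0.533). Their sign follows from that layout and says nothing about the plasmids.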

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

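Chosen only after the result was seen were the tests of a swap, of the sequencing lane and of younger animals or a wrong age label for the first day-5 libraries, those of the feeding construct and of the touch neuron programme for lin-32, that of lane 2 for L4440 day-1 replicate 2, and all counts of other splits.

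By the interaction test of plasmid and age, 24 gene lists passed for M05B5.5 and 25 for T14F9.5 at the preset correlation. With an estimated correlation 0 of either held, and the M05B5.5 interaction cannot be parted from lane. Ribosomal proteins led for both plasmids by adjusted p, not by size, with median interactions of 0.88 and 0.84. Without L4440 day-1 replicate 2 these were 0.31 and 0.25, and without that library and the first day-5 libraries 0.28 and 0.24, so most of both medians rests on 1 control library.

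The first day-5 library of each plasmid lay close to the day-1 libraries. A swap between day-1 and day-5 libraries would leave a day-1 library out of place, and 0 day-1 libraries correlated better with the day-5 libraries, which argues against it. The sequencing lane is argued against as well, since 3 of 3 other day-5 libraries on the same lanes correlated better with the day-5 libraries. Of 18 gene lists that part the ages in the other libraries, 17 put all 3 of these libraries with day 1. The libraries were picked because they lie near day 1, and the lists were picked from the same counts. This number was therefore largely given beforehand and lends no weight to a cause. Animals younger than labelled or a wrong age label may account for these libraries, but this was not shown. On the third principal component, with 6.55% of the variance, these 3 libraries lay together at 22.5 to 23.7, outside the day-1 libraries (-19.8 to 9.12), while the other day-5 libraries ran from -35.1 to 26.7. They are thus not the same as the day-1 libraries in every respect, and that difference was not explained. Younger animals and a wrong label cannot be told apart from the counts, and a biological difference between cultures of 1 age was not tested.

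lin-32 counts were higher in 3 of 3 libraries labelled T14F9.5 at day 5 than in every L4440 library of that age, though in the first of them only by 38 against 34 counts, and that library was below every L4440 day-1 library. Reads from a neighbouring gene are argued against only for the tested genes within 5 kb. Their log2 fold changes were 0.21 (hex-1, SE 0.39) and 0.093 (T14F9.2, SE 0.14). The noncoding genes T14F9.13, T14F9.t1 and T14F9.8 in that window were not tested. Reads from the feeding construct could be counted at lin-32. At day 1, 0 of 3 libraries stood above every L4440 library, but this rests on L4440 day-1 replicate 2, at 2.57 CPM. The libraries labelled T14F9.5 held 2.45, 2.18 and 1.96 CPM, above L4440 day-1 replicates 1 (1.74 CPM) and 3 (1.83 CPM). An uptake of bacteria that differs with age also keeps this explanation open. Higher lin-32 transcription with its touch neuron programme is open too: the median log2 fold change of touch receptor neuron genes was 0.15 and the list did not pass. These last explanations cannot be told apart, since the counts do not give the position of reads within the gene.

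L4440 day-1 replicate 2 lay apart from the other day-1 libraries, with a slope of -0.61 log2 units per doubling of gene length (28.4% of its variance). Library size is argued against, since the slope was -0.607 after all libraries were thinned to the smallest total. Lane 2 is argued against, since the lowest slope of the other day-1 libraries on it was -0.0173. A gene length trend as the whole cause is argued against too: with the trend taken out its median distance was 1.04 (root mean square log2; 1.27 before), where those of the other day-1 libraries were at most 0.584. No biological explanation was tested.

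Where 3 libraries were set against 3 there are 10 splits, too few for a share under 0.05. Where the real count is 0 every split must reach it, so 10 of 10 splits did by necessity and the share says nothing for M05B5.5 at day 1 (real 0, highest other 0), M05B5.5 at day 5 (0 and 0), T14F9.5 at day 1 (0 and 3985), T14F9.5 at day 5 (0 and 18) and the direct comparison at day 5 (0 and 1). As many genes as in the real split came in 1 of 10 splits, the real one itself, for age in L4440 (2332 and 0) and the direct comparison at day 1 (1 and 0). The split that called 3985 genes put L4440 day-1 replicates 1 and 2 with T14F9.5 day-1 replicate 2, the libraries whose slopes against gene length were -0.23, -0.61 and -0.17, which points to a structure of the samples other than plasmid. This split also holds together the pair with the same index and lane, L4440 day-1 replicate 1 and T14F9.5 day-1 replicate 2. For the interactions the real counts were 0, which all of the 100 splits drawn for each (100 of 100) must reach, so the count of splits says nothing about chance. The highest other counts there, 222 for M05B5.5 and 3301 for T14F9.5, point to such a structure too.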

How the results depend on the processing

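Alternatives chosen after seeing the data were the gene length offset, controls divided between the plasmids, the surrogate variables, a block for the first day-5 library of each plasmid, and the fits without the first day-5 library of each plasmid or without those and L4440 day-1 replicate 2 (below, without 4 libraries). For the correlation of the responses, leaving out L4440 day-1 replicate 2 was chosen likewise. No paired analysis was possible because the labels give no replicate numbers, and those used here only follow the order of the samples. The first day-5 libraries stood apart together, and the block for them was picked from the same counts, so its p-values do not allow for that choice. The same holds for the fits that leave those libraries out. For age this choice also widens the difference under test. The labels give no batch other than lane. As a fixed term lane could be estimated for 5 comparisons, where it called 0 genes, as the main fit did. It could not be estimated for M05B5.5 against L4440 or T14F9.5 at day 1, for age in L4440 or for the M05B5.5 interaction. There lane is confounded with the groups, so those results cannot be parted from lane. With lane as a random term the correlation within lanes was -0.24, and that fit cannot part them either. A negative value lowers the standard errors where the compared groups share no lane, so the counts of that fit lend no weight there. Upper-quartile factors moved the median of all genes by -0.13 for age, -0.10 for M05B5.5 at day 1 and 0.10 for the interactions. Of the RPKM values 94.4% were divided by another library's total, so the counts in the RPKM settings do not show how firm a result is. The cause of the changes given here was not tested unless stated. With 1 library left out a group holds 2.

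Of 3860 values of 165 single-gene results, 2891 stayed on their side of the threshold, 773 lost their call, 191 gained one and 5 reversed. Of the 2891, 147 were uncalled and had the other sign. The reversed ones belong to age in L4440. With the gene length offset drh-1 was at -0.086 and sdc-1 at -0.25. With that offset and without the first day-5 libraries drh-1 was at -0.048, sdc-1 at -0.26 and vit-6 at -0.80 (adjusted p = 0.0301, with 0.0301 to 0.990 over its alternatives). For lists, the one reversal by the direction that camera gives was the DAF-16 list for M05B5.5 at day 5, at -0.029 without M05B5.5 day-5 replicate 3 (adjusted p = 0.644, with 2.2e-10 to 0.818 over its alternatives), where leaving out each library gave -0.029 to 0.713. Medians of other lists changed sign while that direction stayed. Collagens for M05B5.5 at day 5 went from -0.12 to 0.045 with the stricter filter, 0.12 without L4440 day-5 replicate 1 and 0.078 without M05B5.5 day-5 replicate 3, and in the direct comparison at day 5 from -0.40 to 0.16 with the stricter filter. Larval moult genes for T14F9.5 at day 5 went from 0.55 to -0.0051 without T14F9.5 day-5 replicate 2. F-box and MATH-BTB families in the direct comparison at day 5 went from -0.017 to 0.0066 without T14F9.5 day-5 replicate 2 and 0.0053 without M05B5.5 day-5 replicate 3. Of planned list values 493 stayed and 58 lost the call, and of added ones 229 stayed and 35 lost it.

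Counts of genes for M05B5.5 against L4440 at day 1 were 2244 with DESeq2, 3515 with limma-voom and lane, 517 with log2(RPKM + 1), 3 with log2(RPKM + 0.1), 0 with every gene above 0 RPKM, 7 with surrogate variables, 0 without the first day-5 libraries, 4 without 4 libraries, 2311 with the block, and 10 with the gene length offset without the first day-5 libraries. Leaving out each library gave 0 to 5042. At day 5 they were 7 with DESeq2, 1 with log2(RPKM + 1), 1 with log2(RPKM + 0.1), 1 with every gene above 0 RPKM, 1 with the length offset, 14 with surrogate variables, 3 without the first day-5 libraries, 4 without 4 libraries, 11 with the block and 13 with the offset without the first day-5 libraries. Leaving out each library gave 0 to 0. For T14F9.5 at day 1 they were 613 with DESeq2 and 1 with surrogate variables, and leaving out each library gave 0 to 3883. At day 5 they were 1 without the first day-5 libraries, 1 without 4 libraries and 1 with the offset without the first day-5 libraries, each time lin-32, and leaving out each library gave 0 to 0.

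For age in L4440 counts were 3807 with DESeq2, 715 with no filter, 0 with the compared groups alone, 4735 with limma-voom and lane, 3 with log2(RPKM + 1), 0 with log2(RPKM + 0.1), 0 with every gene above 0 RPKM, 0 without the pair sharing index and lane, 0 with the length offset, 401 with surrogate variables, 4495 without the first day-5 libraries, 4548 without 4 libraries, 6240 with the block, and 4854 with the offset without the first day-5 libraries. Leaving out each library gave 0 to 5533. RLE factors (2335), upper-quartile factors (2931) and the stricter filter (2478) stayed within 1.5 times.

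For M05B5.5 against T14F9.5 at day 1 counts were 3 with DESeq2, 6 with the compared groups alone, 0 with each of the 3 RPKM settings, 0 without the pair sharing index and lane, 9 with surrogate variables, 2 without the first day-5 libraries, 4 without 4 libraries, 4 with the block and 4 with the offset without the first day-5 libraries. Leaving out each library gave 0 to 1. At day 5 they were 16 with DESeq2, 1 with RLE factors, 1 with no filter, 1 with each RPKM setting, 1 with the offset, 32 with surrogate variables, 13 without the first day-5 libraries, 20 without 4 libraries, 14 with the block and 17 with the offset without the first day-5 libraries. Leaving out each library gave 0 to 2. For the interactions, M05B5.5 gave 3 with the offset without the first day-5 libraries, and leaving out each library gave 0 to 2128. T14F9.5 gave 0 in every fit of all libraries or without the first day-5 libraries, the block included, and 0 to 599 when leaving out each library.

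Lists past the threshold numbered 0 with an estimated correlation in all 9 comparisons, and with the block their numbers stayed within 1.5 times in all 9. With the length offset they were 6 and 12 for M05B5.5 and T14F9.5 at day 1, 11 for age, 4 for the direct comparison at day 1 and 5 for the T14F9.5 interaction. With the offset without the first day-5 libraries they were 7 and 15 at day 1, 5 for the direct comparison at day 1 and 9 for the T14F9.5 interaction. With surrogate variables they were 8 and 14 at day 1, 23 and 23 at day 5, and 12 and 15 for the interactions. Without 4 libraries they were 23 and 17 at day 5 and 14 for the T14F9.5 interaction. With no filter they were 6 for T14F9.5 at day 5 and 16 for the direct comparison at day 5. Leaving out each library gave 17 to 24 for M05B5.5 at day 1, 8 to 23 at day 5, 17 to 26 for T14F9.5 at day 1, 9 to 22 at day 5, 14 to 23 for age, 5 to 14 and 12 to 19 for the direct comparisons, and 20 to 29 and 15 to 25 for the interactions.

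The correlation of the responses at day 1 was 0.610 with no filter and 0.947 with the stricter filter. Of the choices made after seeing the data, leaving out L4440 day-1 replicate 2 gave 0.763. With the controls divided between the plasmids the mean correlation at day 1 was 0.543. At day 5 it was 0.473 with no filter. With divided controls its mean was -0.408, a sign that follows from the layout of the day-5 groups.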

Other observations

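Chosen after the result was seen were the pooled comparison, its test for F-box genes and its splits.

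With both ages pooled, 12 genes were lower and 0 higher in the 6 M05B5.5 libraries than in the other 12 libraries (edgeR, 14735 genes). hlh-2 fell by 1.75 ± 0.19 on the log2 scale, from 55.1 ± 11.5 CPM (n = 12) to 16.8 ± 7.84 CPM (n = 6; adjusted p = 0.000894). F21D9.1 fell to 0.283 ± 0.133 CPM from 1.25 ± 0.375 CPM (-2.2, adjusted p = 0.000894), and arrd-1, an arrestin-domain gene, to 6.78 ± 2.97 CPM from 20.3 ± 5.66 CPM (-1.63, adjusted p = 0.0135). ces-1, a Snail-type factor that controls the death of certain neurons, fell by 2.39 at a level of 0.0656 CPM against 0.392 CPM. F58D2.1 and Y17D7C.4, annotated pseudogenes, and linc-12, a long noncoding RNA gene, are the others outside the F-box family. The F-box genes were fbxb-65 (-2.14), fbxb-42 (-1.43), fbxb-104 (-1.15), fbxb-72 (-1.02) and fbxb-44 (-1.0). Of the 12, ces-1 and Y17D7C.4 were not lower in every M05B5.5 library than in every other library of the same age at both ages, and the other 10 were. The 12 genes were chosen after their values were seen.

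The F-box and MATH-BTB list holds 298 tested genes, and 5 of the 12 belong to it. A hypothesis that the family is over-represented was drawn from these same genes, so a Fisher's exact test on them (one-sided, p = 2.31e-06) is void and does not support it. It also takes genes as independent, and reads shared between similar F-box genes may link them: fbxb-42 and fbxb-44 lie next to each other on chromosome II. Of 100 splits of the libraries within age, which include the real one, 6 gave at least as many genes as the real split, itself among the 6. The real split gave 12 genes and the highest other 2160. Chance is therefore not excluded for the number of genes, and the highest points to a structure of the samples.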
